A study of Mus musculus with 17 samples.

How the data were processed

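The study sequenced poly(A)-selected RNA from mouse liver cells in 17 libraries, which the labels place in 5 groups: early hepatocellular carcinoma (HCC) cells with Mef2d knocked out (KO, 3 libraries), the same kind of cells with wild-type Mef2d (WT, 3 libraries), normal liver cells (3 libraries), and Kupffer cells, the resident macrophages of the liver, labelled KC1 (4 libraries) and KC2 (4 libraries). Per the labels' protocols, total RNA was extracted with TRIzol and stranded libraries were prepared by an automated protocol. The protocol names hepatocytes among the cells extracted, while the sample labels call the control group normal liver cells.

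The authors deposited expected counts per gene, which are estimates of the reads from each gene and need not be whole numbers. Per the submitters' processing notes, the tools were FastQC, HISAT and RSEM and the genome build was mm10, with no versions or roles. The annotation and any gene filter are not given in the sources used here. Between 31.8% and 84.7% of the values in a library, zeros included, were exactly whole as printed with 2 decimals, and library totals differed. The values were taken as unscaled. RSEM divides reads that fit several genes by a model, so the values of near-identical paralogs (the prolactin family, Akr1c genes, Orm1 and Orm2, Mt1 and Mt2, Hspa1a and Hspa1b, the alpha globins, classical MHC genes and zinc finger clusters) are uncertain as single genes. The kit kept strand, but whether counting used it is not given, so overlapping genes are uncertain too.

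There were 3 tables, 1 for each comparison, with 17140 genes in both early HCC tables and 18185 in the Kupffer cell table. The 2 early HCC tables list the same 17140 genes, and each of these had a count in at least 1 KO or WT library, while 1665 had none in the normal liver libraries. The tables used here therefore cannot show genes that were transcribed in normal liver cells alone, and the number of genes lower in early HCC than in normal liver cells is a minimum. The WT values in both tables were identical. A spreadsheet had turned 25 gene symbols of each table into dates, and these were restored from the gene identifiers. Identifiers matched the RefSeq annotation of GRCm38 (the assembly of build mm10) for 99.7% of genes, which gave chromosomes and positions, counted from 1. No transcript of the mitochondrial genome had a row. Columns that could not be assigned to a sample numbered 0.

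Expected counts were rounded to whole numbers. Each comparison was fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, the filterByExpr filter) in R 4.3.3, using only the libraries of its 2 groups. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05, and calls were counted again with an absolute log2 fold change of at least 1. Directions are KO relative to WT, early HCC (the WT libraries) relative to normal liver, and KC2 relative to KC1. Levels are CPM, the share of a gene in the library total (times its TMM factor) on the usual scale of that unit, as mean ± SD. A group with no count of a gene was set at a floor of 3 counts over the group and the fold is given as "at least". A group with 1 to 3 counts is given as a ratio of counts with a 95% interval. These intervals and floors cover counting error only, since the reads carried no molecular identifiers.

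Library totals ran from 15353249 to 18637765 expected counts, and a floor of 3 counts in 1 library corresponded to between 0.150 and 0.208 CPM. Fitted common biological coefficients of variation were 0.0340 for KO against WT, 0.0371 for early HCC against normal liver and 0.267 for KC2 against KC1. Pairs of replicates were compared by a chi-square test over genes. The chi-square per degree of freedom was 1.86 to 4.90 among early HCC and normal liver replicates, 13.3 to 43.4 among KC1, 24.6 to 40.9 among KC2 replicates 2 to 4, and 145 to 186 for pairs with KC2 replicate 1. No pair differed by less than sampling noise, so all libraries were kept as replicates. The labels do not say that replicates of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

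Before the data were examined, 38 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists were tested with camera in limma 3.58.1 on voom log2 values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison that had at least 3 tested members. Their members were also counted by the gene test, adjusted over all genes and over the list alone. The lists were: MEF2 factors and class IIa histone deacetylases, proliferation, oncofetal and liver tumour markers, hepatocyte identity, xenobiotic metabolism, bile acid synthesis and transport, urea cycle and gluconeogenesis, glycolysis, fatty acid oxidation, cholesterol and fatty acid synthesis, lipid uptake, oxidative phosphorylation, p53 targets, NRF2 targets, beta-catenin targets, unfolded protein response, acute phase response, secreted signals to macrophages and lymphocytes, mesenchymal genes and matrix, interferon response, MHC class I and MHC class II presentation, inflammatory cytokines and NF-kB targets, immune checkpoint ligands, lipid-associated macrophage genes, Kupffer cell identity, Kupffer cell subset markers, markers of sinusoidal endothelial cells, stellate cells, cholangiocytes, T and NK cells, B cells, neutrophils, monocytes and red blood cells, immediate early and dissociation genes, mitochondrial transcripts, and sex-linked genes.

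Named genes are the MEF2 factors (with Mrc1 and Esam for Kupffer cells), then the 8 genes with the largest fold changes each way among calls whose groups did not overlap and whose higher group averaged at least 10 CPM (predicted genes and immune receptor segments left out), then up to 3 called members of a list past the camera threshold or with at least 1 in 3 of its tested members called. The latter are the 2 largest changes among members of at least 1 CPM and the most abundant of the rest. A few genes outside this rule are named as such, and some results that the rule selects are not reported here. The tests of technical explanations used the same CPM. The alternatives were DESeq2 1.42.0, RLE and upper-quartile scaling, limma-voom, no filter, a filter at 10 CPM, the replicate number as a block, and leaving out each library in turn. For lists they were an estimated correlation, fry, the block and each library left out.

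Each step was tested on simulated counts with 50 genes planted at each of 4 fold sizes, and 58%, 68% and 0% of those at the smallest size were recovered in the 3 comparisons, in the order above. With the KO and WT settings (12093 genes), 78% of genes changed 1.5-fold, 94% of those changed 2-fold and 98% of those changed 4-fold were recovered, with 16 calls among 11893 unchanged genes. With the early HCC and normal liver settings (12697 genes) these shares were 86%, 94% and 98%, with 14 calls among 12497. With the Kupffer cell settings (12774 genes) they were 0%, 32% and 84%, with 4 calls among 12574. In each of the 3 simulations camera called the planted list and 0 of 50 unchanged lists. Simulated genes were drawn independently and few were changed. These results therefore do not show how often camera calls unchanged lists of correlated genes. Chromosome shifts were measured as the median log2 fold change of a chromosome's genes minus that of all genes, against 10000 random gene sets of the same size. In simulations with 1 shifted chromosome the shift was recovered, and 1, 2 and 0 of the other chromosomes were called in the 3 settings. Genes were independent there too. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.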

Results

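RNA was measured in 17 mouse liver cell libraries. Early HCC cells from mice induced with DEN (as the labels abbreviate it, in liver work usually the carcinogen diethylnitrosamine) gave 3 libraries with Mef2d knocked out and 3 with wild-type Mef2d. Mef2d encodes a transcription factor of the MEF2 family. Normal liver cells gave 3 libraries and Kupffer cells gave 4 KC1 and 4 KC2 libraries. Library totals were 16604606 to 17683298 expected counts in early HCC cells, 18467849 to 18637765 in normal liver cells and 15353249 to 16743459 in Kupffer cells. The design names a comparison of KO with WT cells and one of KC1 with KC2, and a separate table pairs the WT libraries with normal liver cells. The series title places these comparisons in a study of how Mef2d-expressing precursor cells and resident macrophages relate in liver tumour formation.

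The first comparison asked which transcripts differed between Mef2d KO and WT early HCC cells. Mef2d itself (gene 17261, chromosome 3, 88141941 to 88172091) was at 69.4, 64.1 and 66.3 CPM in the 3 KO libraries and at 99.8, 98.3 and 105 CPM in the 3 WT libraries. The groups did not overlap, and the KO mean of 66.6 ± 2.68 CPM was 1.52-fold below the WT mean of 101 ± 3.55 CPM (SD, n = 3 each). The log2 fold change was -0.60 ± 0.04 (SE), with an adjusted p of 7.17e-09 by the edgeR quasi-likelihood test. The worksheet with these values is named "H22 C1C17 AML sh vs ctrl". H22 is also the name of a mouse hepatoma line, and the last words are usual for a knockdown. The parts C1C17 and AML were not interpreted here, and whether any library came from a cell line was not tested. The sample labels and column names give KO and WT early HCC cells and were followed here. The labels do not say which part of the gene was altered, and counts per gene do not show whether the remaining transcripts encode a working protein. Mef2a was 1.37-fold higher in KO cells (90.2 ± 2.19 against 66.0 ± 7.42 CPM), Mef2b was at 0.516 ± 0.467 against 0.665 ± 0.0648 CPM (adjusted p = 0.589), and Mef2c was too low to be tested, at 0.115 ± 0.0995 against 0.307 ± 0.0864 CPM. Among the class IIa histone deacetylases that bind MEF2 factors, Hdac7 was 1.97-fold lower in KO cells. In the list of MEF2 factors and these deacetylases 1 of 7 tested members rose and 2 fell.

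**Figure D1:**
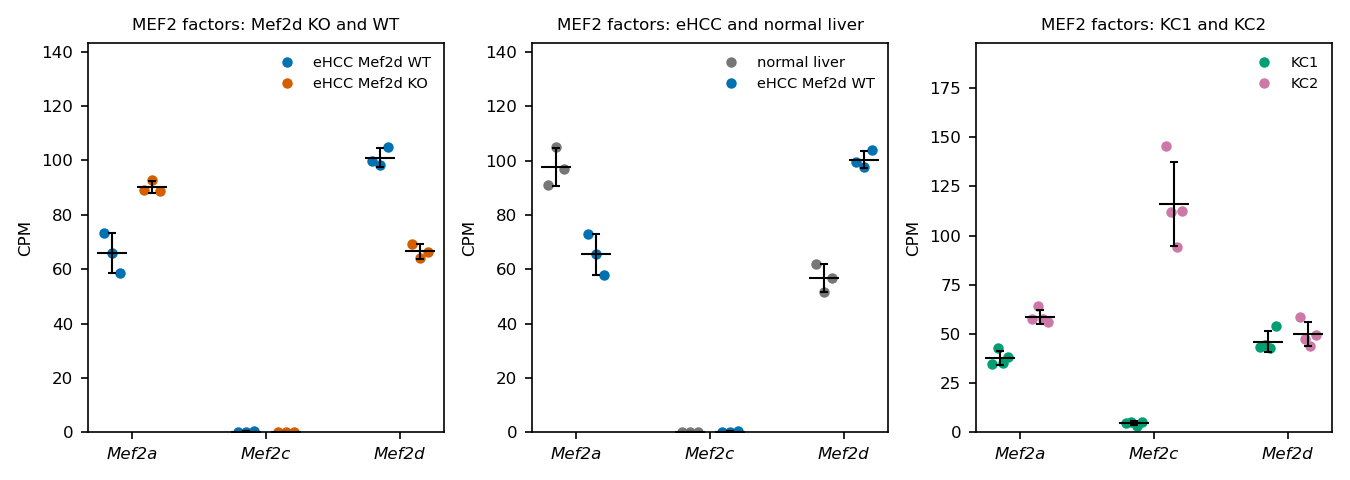
CPM of Mef2a, Mef2c and Mef2d in each library (points) with group means and SD (lines). Mef2d lay between 64.1 and 69.4 CPM in the KO libraries and between 98.3 and 105 CPM in the WT libraries, and Mef2c was at 116 ± 21.4 CPM in KC2 against 4.68 ± 0.949 CPM in KC1.

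Cell cycle genes were lower in KO cells. Of 32 tested proliferation genes 30 fell and 0 rose, among them Top2a, the topoisomerase of dividing cells (607 ± 14.6 against 1051 ± 29.6 CPM, 1.73-fold), Ccnb2, a mitotic cyclin (2.64-fold), and Tyms, which makes thymidylate for DNA synthesis (2.10-fold). This list passed the camera test (adjusted p = 1.75e-12) and kept its call with an estimated correlation (adjusted p = 0.0282). Of 27 genes of oxidative phosphorylation 18 fell and 3 rose, with Ndufs1 of complex I 1.62-fold lower and Atp5b of ATP synthase 1.27-fold lower, while Ndufa1 was 1.62-fold higher. The list passed camera at an adjusted p of 0.00556, and its adjusted p was 0.327 with an estimated correlation. Genes of the unfolded protein response went the other way, with 13 of 19 higher and 1 lower. Asns, the asparagine synthetase of the amino acid response, was 2.30-fold higher at 168 ± 3.88 against 73.1 ± 0.915 CPM, Dnajb9 was 1.85-fold higher and Hsp90b1 was 1.11-fold lower. Camera gave an adjusted p of 0.00556, and the adjusted p was 0.359 with an estimated correlation. All 4 tested cholangiocyte markers rose, namely Epcam (2.37-fold, 36.6 against 15.5 ± 0.657 CPM), Cldn4 (6.26-fold, from 0.306 ± 0.181 CPM), Spp1 (1.28-fold) and Krt19 (32.3 ± 1.05 against 15.3 ± 1.49 CPM, outside the rule for named genes and chosen after its values were seen), with an adjusted p of 0.0133 that became an adjusted p of 0.359 with an estimated correlation.

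**Figure D2:**
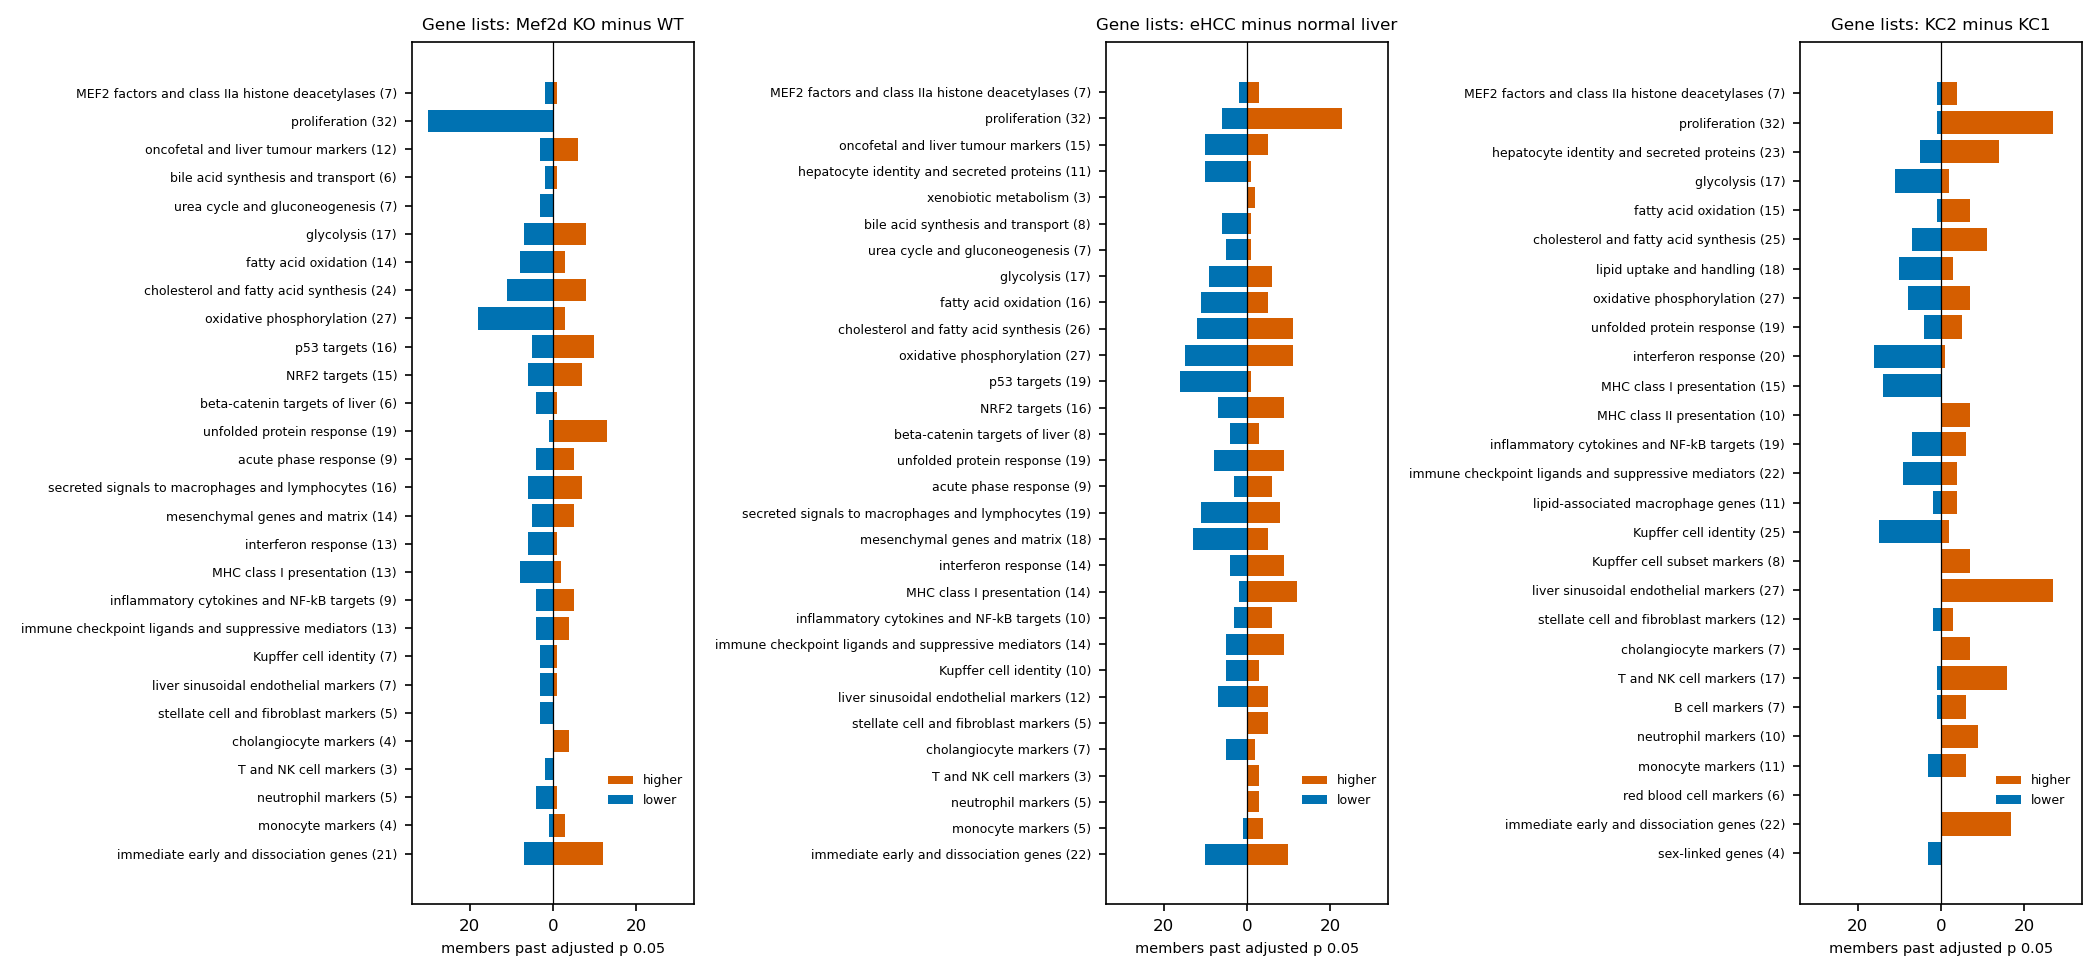
Members of each gene list that were higher (right) and lower (left) at an adjusted p under 0.05, with the number tested in brackets. In KO cells 30 of 32 proliferation genes were lower, in early HCC cells 23 of 32 were higher than in normal liver cells, and all 27 endothelial markers were higher in KC2.

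Metabolic lists other than oxidative phosphorylation did not pass the list test. The transcriptional coactivator Ppargc1a, a driver of mitochondrial and gluconeogenic programmes, was nevertheless almost absent from KO cells, at 0.369 ± 0.0904 against 73.4 ± 2.24 CPM (log2 fold change -7.62 ± 0.11, adjusted p = 1.19e-16). It belongs to the list of urea cycle and gluconeogenesis, in which 3 of 7 tested members fell and 0 rose, the others being Glul (1.13-fold) and Asl (1.15-fold). In fatty acid oxidation 8 of 14 members fell and 3 rose (13 changed when adjusted over the list alone), including both subunits of the trifunctional protein, Hadha (1.69-fold lower) and Hadhb (1.86-fold lower). Glycolysis genes split, with 8 of 17 higher and 7 lower. The glucose transporter Slc2a1 was 2.17-fold higher, whereas Pkm and Pfkp were 1.43-fold and 1.79-fold lower. Cholesterol and fatty acid synthesis had 8 of 24 higher (Scd1, 561 against 431 CPM) and 11 lower (Elovl6 1.64-fold). Bile acid genes had 1 of 6 higher (Acox2, 1.91-fold) and 2 lower (Cyp7a1 2.01-fold, Amacr 1.49-fold). Counts over each list alone were the same as over all genes for every list of this comparison except fatty acid oxidation.

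Genes for secreted signals and matrix changed in both directions. Areg, an EGF receptor ligand, was at 61.0 ± 2.67 CPM in KO and 2.39 ± 0.568 CPM in WT cells (25.4-fold), and the monocyte chemoattractants Ccl2 and Ccl7 were 13.2-fold and 9.32-fold higher. In all, 7 of 16 tested signals to macrophages and lymphocytes rose and 6 fell. Inflammatory genes had 5 of 9 higher and 4 lower, with Nfkbia 1.33-fold lower. Acute phase genes had 5 of 9 higher (Orm1, 6.89-fold) and 4 lower. Mesenchymal genes had 5 of 14 higher, with Fn1 at 2510 against 1111 ± 51.1 CPM, and 5 lower, with the protease Mmp9 3.38-fold lower. Of 12 tumour markers 6 rose, including the stem cell marker Cd44 (2.11-fold), and 3 fell, including the fetal growth factor Igf2 (3.89-fold, 10.6 ± 0.658 against 41.2 ± 0.920 CPM) and Lcn2 (3.36-fold). None of these lists passed camera.

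The lists of MHC class I, interferon, checkpoint, p53, NRF2, beta-catenin and immediate early genes did not pass camera either. In MHC class I presentation 8 of 13 genes fell and 2 rose (adjusted p = 0.0871), with the peptide transporter Tap2 1.93-fold lower and H2-K1 1.31-fold lower. Interferon genes had 6 of 13 lower (Oasl2, 3.44-fold) and 1 higher, and checkpoint ligands had 4 of 13 lower (Lgals9 1.86-fold, Cd47 1.15-fold) and 4 higher (Cd276, 1.80-fold). Targets of p53 had 10 of 16 higher (Perp 2.74-fold, Plk2 1.92-fold, Trp53inp1 1.52-fold) and 5 lower (adjusted p = 0.0879). Targets of NRF2 had 7 of 15 higher (Slc7a11 1.64-fold, Nqo1 1.51-fold) and 6 lower. Liver beta-catenin targets had 4 of 6 lower, with the Wnt deacylase Notum 2.15-fold lower, and 1 higher. Immediate early genes had 12 of 21 higher (Atf3 36.3 against 10.3 CPM, Fos 3.01-fold) and 7 lower.

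Genes with the largest differences that were higher in KO cells included Prl8a9 and Prl2c2 of the prolactin family and Akr1c12 on chromosome 13, Lrrc47, Slc25a33 and Pla2g5 on chromosome 4, and Zfp936 on chromosome 7. Lrrc47 (gene 72946, 154011803 to 154021512) was at 31.8 ± 4.02 CPM in KO and 0.0945 ± 0.118 CPM in WT cells. Its mean in normal liver cells was 70.1 CPM, and it lies in a run of neighbouring genes near zero in WT cells, described further below. Prl8a9 had 2 counts over the WT libraries, a count ratio of 373 (95% interval 103 to 3085). Those lower were Ppargc1a, Cd28, Trim30d and, all on chromosome 9, Vwa5a, Cyp11a1, Rec114, Plscr2 and Stra6, with Cd28 at 0.0956 ± 0.0873 against 10.2 ± 0.699 CPM and Cyp11a1 at 1.04 ± 0.255 against 27.2 ± 1.17 CPM. After these values had been seen, the median log2 fold change was computed per chromosome. Genes of chromosome 4 (760 tested, 83.0% higher in KO) had a median 0.49 above that of all genes, where random sets of as many genes lay between -0.03 and 0.03, and chromosomes 7 and 9 had medians of 0.24 above and -0.24 below (adjusted p = 0.00025 each, from the smallest p that 10000 random sets allow). Chromosomes 1, 2, 5, 6 and 10 had the same adjusted p with medians of -0.11, -0.07, -0.09, 0.10 and 0.13, and 14 of 20 chromosomes were under 0.05. The same test also called chromosomes in KC2 against KC1, among them 6 (0.24, adjusted p = 0.002) and X (0.23, adjusted p = 0.008), though not 4 (-0.05, adjusted p = 0.395). A call by this test alone therefore does not set a comparison apart.

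**Figure D3:**
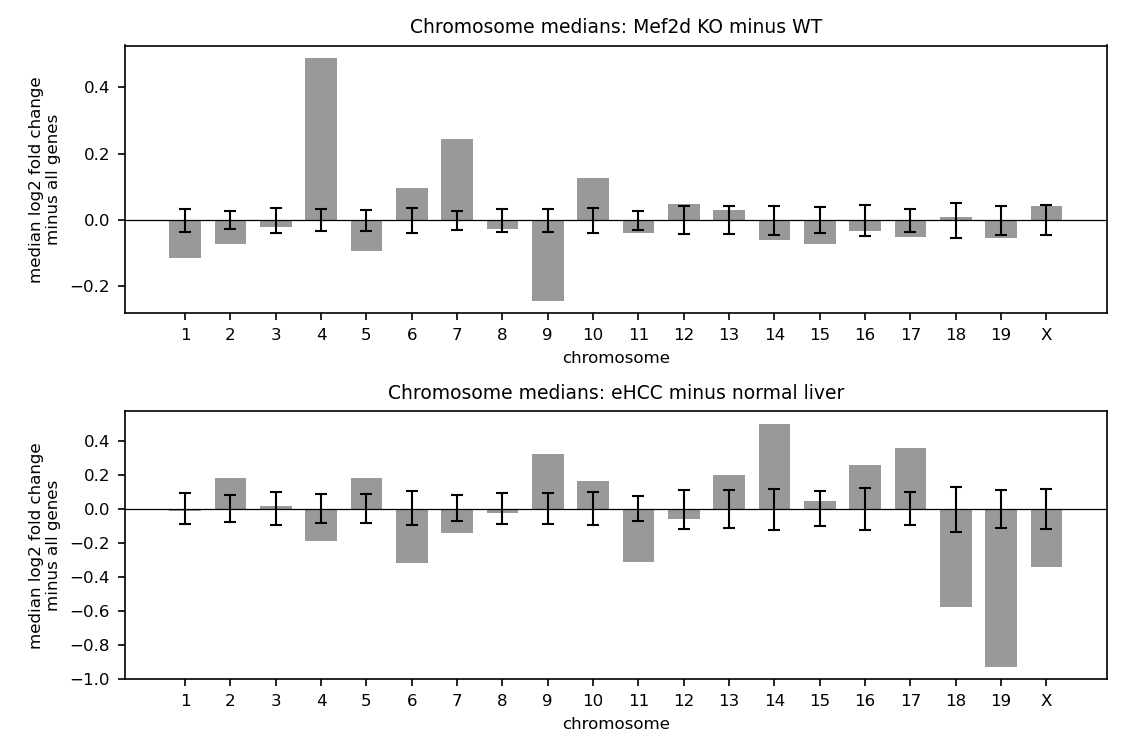
Median log2 fold change of each chromosome's tested genes minus the median of all genes (bars), with the interval of random gene sets of the same size (lines). Chromosome 4 stood at 0.49 for KO against WT, and chromosome 19 at -0.93 for early HCC against normal liver.

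In total 7800 of 12093 tested genes differed between KO and WT cells, 3911 higher and 3889 lower, and 438 and 488 of these by at least 2-fold. With each gene centred on its chromosome's median, a step chosen after the data were seen, 357 were higher and 487 lower by at least 2-fold, and the numbers on chromosome 4 went from 102 higher and 14 lower to 41 and 37. Replicates within a group differed little, so that many small differences passed the test: the median absolute log2 fold change over all tested genes was 0.28.

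The second comparison set early HCC cells (the WT libraries) against normal liver cells. Mef2d was 1.76-fold higher in early HCC cells, at 100 ± 3.24 against 56.9 ± 5.05 CPM (log2 fold change 0.82 ± 0.06, adjusted p = 3.52e-10), with 99.4, 97.7 and 104 CPM in the early HCC and 61.9, 51.8 and 57.0 CPM in the normal liver libraries. Mef2a was 1.49-fold lower (65.5 ± 7.59 against 97.6 ± 7.05 CPM), Mef2b was at 0.661 ± 0.0655 against 0.666 ± 0.131 CPM (adjusted p = 0.961), and Mef2c was not tested (0.305 ± 0.0850 against 0.0916 ± 0.0637 CPM). Hdac4 was 1.91-fold higher and Hdac7 was 1.63-fold lower. In this list 3 of 7 members rose and 2 fell.

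Proliferation genes were higher in early HCC cells, with 23 of 32 higher and 6 lower. They were abundant in the normal liver libraries as well, where mean CPM over the list summed to 4817 against 6655 in early HCC cells. Top2a was at 608, 679 and 625 CPM in the normal liver libraries, so this is not a comparison with cells that lack cell cycle transcripts. The mitotic genes Ccnb1 (395 ± 8.61 against 132 ± 6.90 CPM), Ube2c (2.82-fold) and Top2a (1.64-fold) were among those that rose, and camera gave an adjusted p of 0.0130 (adjusted p = 0.314 with an estimated correlation). Targets of p53 were lower, with 16 of 19 lower and 1 higher (adjusted p = 0.00132, and adjusted p = 0.314 with an estimated correlation). The cyclin gene Ccng1 was 18.4-fold lower, at 35.4 ± 2.89 against 652 ± 25.6 CPM, the ectodysplasin receptor Eda2r was at 0.308 ± 0.155 against 60.4 ± 4.63 CPM, and Btg2, which restrains cell division, had 0 counts in early HCC cells and was at least 361-fold lower. Genes of MHC class I presentation were mostly higher, with 12 of 14 higher, including Tap1 (count ratio 304, 83.8 to 2518) and the immunoproteasome gene Psmb9 (at least 78.7-fold). The 2 lower members included B2m, the light chain of class I molecules, which fell 2.76-fold to 92.6 ± 1.69 CPM. Camera gave an adjusted p of 0.0130, and the adjusted p was 0.314 with an estimated correlation.

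Hepatocyte genes were lower in early HCC cells, but their levels were low or moderate in the normal liver libraries as well. Of 11 tested members of the hepatocyte list 10 fell and 1 rose, with 10 of the 25 list genes having no row. The transcription factors Hnf4a (119 ± 4.41 CPM) and Foxa2 (34.9 ± 1.41 CPM) and the retinol carrier Rbp4 (180 ± 6.55 CPM) were present in normal liver cells and at 0.151 ± 0.115, 0.0561 ± 0.0562 and 0.0760 ± 0.0855 CPM in early HCC cells. Albumin, the main secreted protein of hepatocytes, was at 2.40 ± 0.260 CPM in normal liver cells, and Krt8, Krt18 and Krt19, keratins of simple and biliary epithelium, were at 1679 ± 53.8, 1229 ± 22.4 and 1081 ± 14.5 CPM. In the WT early HCC libraries, scaled with the KO libraries, Alb was at 0.133 CPM and these keratins at 50.2, 67.3 and 15.3 CPM. Alb and these keratins lie outside the rule for named genes and were chosen after their values were seen. Camera gave the list an adjusted p of 0.0445, which became an adjusted p of 0.567 with an estimated correlation. Leaving out WT replicate 1 or 2 (adjusted p = 0.0507 and 0.0528) or using the replicate number as a block (0.0590) ended the call.

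Other liver and metabolic lists did not pass camera. In bile acid synthesis and transport 6 of 8 genes fell and 1 rose, with the bile acid receptor Nr1h4 103-fold lower (1.05 ± 0.185 against 108 ± 2.14 CPM) and the sterol hydroxylase Cyp27a1 lower by a count ratio of 298 (102 to 1450). Xenobiotic metabolism had 3 tested genes, of which Por rose 1.27-fold and Cyp2e1 2.53-fold. Cyp2e1 was under 1 CPM in both groups, and its adjusted p went from 0.0149 to 0.0790 without normal liver replicate 2 and to 0.0844 without WT replicate 1. Fatty acid oxidation had 11 of 16 lower, with Decr1 at 1 count in early HCC cells (count ratio 2021, 362 to 79872) and the lipid-sensing receptor Ppara at 0 counts (at least 174-fold lower), and 5 higher. Urea cycle and gluconeogenesis had 5 of 7 lower (Got1 2.07-fold) and 1 higher, Ppargc1a, at 72.9 ± 1.98 against 4.87 ± 0.414 CPM (14.9-fold). Glycolysis had 6 of 17 higher and 9 lower, and its median and mean log2 fold changes had opposite signs (-0.13 and 1.22). The glucose transporter Slc2a3 was at 1366 ± 18.7 CPM in early HCC cells and 0.457 ± 0.0287 CPM in normal liver cells, and Hk2 was 112-fold higher, whereas Gapdh was 1.42-fold lower. Cholesterol and fatty acid synthesis had 11 of 26 higher and 12 lower, with Gpam under 0.1 CPM in early HCC cells and at 143 ± 1.23 CPM in normal liver cells. Oxidative phosphorylation had 11 of 27 higher (Atp5b, 1.56-fold) and 15 lower (Sdhb, 3.82-fold).

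Tumour, stress and signalling lists went both ways. Tumour markers had 5 of 15 higher, with Epcam at 15.3 ± 0.660 CPM in early HCC cells and 0 counts in normal liver cells (at least 280-fold), and 10 lower, with the imprinted gene Peg3 at 0.267 ± 0.0377 against 441 ± 6.56 CPM. Mesenchymal genes had 13 of 18 lower (Vim 1.32-fold, Thbs1 by a count ratio of 1072, 192 to 42381) and 5 higher (Mmp9, count ratio 1448, 495 to 7022). Beta-catenin targets had 3 of 8 higher, with Notum at 45.2 ± 2.33 CPM against 1 count (count ratio 2477, 444 to 97865), and 4 lower. NRF2 targets had 9 of 16 higher (Txnrd1, 1.73-fold) and 7 lower (Gstm1, 27.1-fold). The unfolded protein response had 9 of 19 higher (Hspa5, the main chaperone of the endoplasmic reticulum, 2.18-fold) and 8 lower (Asns, 9.81-fold). Acute phase genes had 6 of 9 higher (Mt2, 10.4-fold) and 3 lower (Cfb, 8.99-fold). Secreted signals had 8 of 19 higher (Cxcl10, count ratio 160, 54.3 to 778) and 11 lower (Ccl2, 59.1-fold). Interferon genes had 9 of 14 higher (Gbp2, 56.5-fold) and 4 lower, inflammatory genes had 6 of 10 higher (Nfkbia, 2.42-fold) and 3 lower (Ptgs2, at least 120-fold), and checkpoint ligands had 9 of 14 higher (Cd47, 3.76-fold) and 5 lower.

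The largest differences were between genes read in one group and nearly without counts in the other. Higher in early HCC cells were Cox7b2 (49.3 ± 2.94 CPM, at least 897-fold), Teddm3 (at least 894-fold), B4galnt4 (at least 719-fold), the G protein regulator Rgs16 (at least 681-fold), Gatm, the first enzyme of creatine synthesis (121 ± 6.01 CPM against 1 count), Angptl2, Lhfp and Cavin3. Lower were Zscan26 (74.7 ± 2.15 CPM in normal liver cells, at least 1306-fold), Ripk4 (at least 810-fold), Ldlrad3, Armcx3, Vsig1, Spats2l, Patj (at least 601-fold) and the ion channel gene Trpa1 (102 ± 3.85 CPM against 1 count). In total 11069 of 12697 tested genes differed, 5570 higher and 5499 lower, and 2576 and 2629 of these by at least 2-fold. Genes without a count in any KO or WT library had no row, so the numbers of lower genes are minimums.

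The third analysis related the first 2 comparisons, which share the WT libraries. Over 11900 genes tested in both, the log2 fold changes of KO against WT and of early HCC against normal liver had a Pearson r of -0.26 and a Spearman rho of -0.23 across genes, which are not independent replicates. Of 6835 genes called in both, 61.7% had opposite directions. Genes higher in early HCC cells and lower in KO cells numbered 2292, where independent lists give 1818, and those lower in early HCC cells and higher in KO cells numbered 1925, where independent lists give 1523. Both higher were 1411 genes (1787 for independent lists) and both lower 1207 (1550). Unchanged groups simulated with shared control libraries gave a more negative r, -0.50 (-0.53 to -0.47 over 20 simulations), and at most 3 genes called in both. The covariance was -0.41 against a simulated -0.0083, a difference of -0.40. The 3 shared libraries cannot be split into 2 sets of at least 2, and the simulation covers the noise of shared controls alone, so a property of these WT cells that enters both comparisons was not separated. Without genes of chromosomes 4, 7 and 9, left out after the chromosome medians were seen, r was -0.23.

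The last comparison asked how KC2 differed from KC1 cells. KC2 cells are a subset usually set apart from KC1 by the mannose receptor Mrc1 and the adhesion molecule Esam. If the cells were sorted on such markers, their difference is not an independent finding. Mrc1 (gene 17533, chromosome 2) was at 840 ± 103 CPM in KC2 and 139 ± 98.1 CPM in KC1 (SD, n = 4 each; log2 fold change 2.59 ± 0.39 (SE), adjusted p = 0.000235), and Esam (gene 69524, chromosome 9) was at 619 ± 179 against 8.75 ± 3.82 CPM (70.7-fold, adjusted p = 6.18e-07). KC1 replicate 2 had 285 CPM of Mrc1, and without it the log2 fold change of Mrc1 was 3.2. Mef2c was 24.7-fold higher in KC2 (116 ± 21.4 against 4.68 ± 0.949 CPM), Mef2a was 1.56-fold higher, and Mef2d was at 49.8 ± 6.15 against 46.2 ± 5.19 CPM (log2 fold change 0.11 ± 0.13, adjusted p = 0.484). Mef2d was at 43.4, 44.3, 43.1 and 53.9 CPM in the KC1 and 58.5, 47.5, 44.0 and 49.3 CPM in the KC2 libraries. Mef2b had 1 count over the KC1 libraries and was not tested. Hdac7 was 9.86-fold higher and Hdac9 was 6.34-fold lower in KC2. The list had 4 of 7 members higher and 1 lower.

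Endothelial genes were higher in KC2 libraries without exception. All 27 tested markers of liver sinusoidal endothelial cells rose, including Dnase1l3, a secreted DNase (8862 ± 3679 against 845 ± 231 CPM, 10.5-fold), Igfbp7 (425-fold, 248 ± 36.1 against 0.575 ± 0.379 CPM) and Adam23 (604-fold). Kupffer cell subset markers had 7 of 8 higher, with Mcam 53.7-fold and Cd55 1.85-fold higher. This subset list holds Mrc1 and Esam, so its result is not independent if the cells were sorted on such markers. Its members Pecam1, Lyve1 and Cdh5 are also expressed by endothelial cells. Kupffer cell identity genes were lower, with 15 of 25 lower and 2 higher (19 changed when adjusted over the list alone). The scavenger receptor Marco fell from 8131 ± 612 to 154 ± 108 CPM, Spic, a transcription factor of iron-handling macrophages, was 41.9-fold lower, and the complement gene C1qb was 2.54-fold lower. Camera gave adjusted p-values of 1.98e-17, 0.000250 and 0.00193 for these 3 lists, and with an estimated correlation they were adjusted p = 0.534, 0.534 and 0.670.

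**Figure D4:**
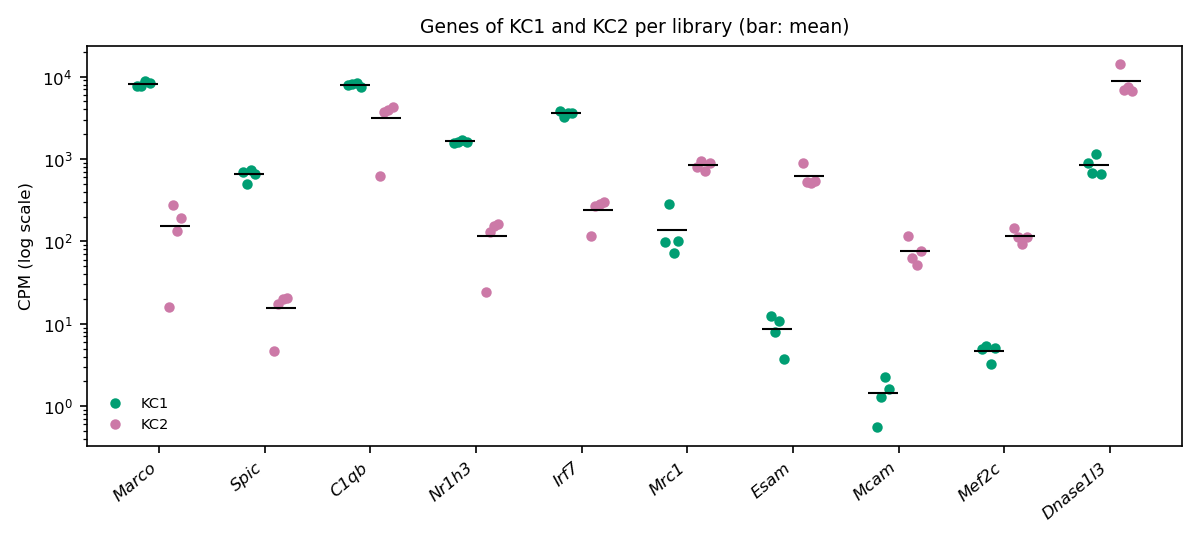
CPM (log axis) of 10 genes in each KC1 and KC2 library (points) with group means (lines). Marco, Spic, C1qb, Nr1h3 and Irf7 were lower and Mrc1, Esam, Mcam, Mef2c and Dnase1l3 higher in KC2, and KC2 replicate 1 had 14354 CPM of Dnase1l3 where the median of the other KC2 libraries was 6838.

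Markers of several other cell types were also higher in KC2. T and NK cell genes had 16 of 17 higher, such as the NK receptor genes Ncr1 (at least 171-fold) and Klrb1c (230-fold), and 1 lower, the chemokine Ccl5, at 119 ± 38.4 against 3723 ± 1009 CPM. Neutrophil genes had 9 of 10 higher (Ltf 37.2 against 0.380 CPM, Camp 122-fold, S100a9 24.8-fold), and all 7 cholangiocyte genes rose, including Epcam (at least 137-fold) and Spp1 (34.1-fold). B cell genes had 6 of 7 higher (Ms4a1 52.8-fold, Cd79a 39.4-fold) and 1 lower (Cd22, 2.60-fold), and monocyte genes had 6 of 11 higher (F13a1, 185 against 10.9 CPM) and 3 lower (Itgam, 7.57-fold), 10 changed when adjusted over the list alone. Hepatocyte genes had 14 of 23 higher (Alb 5.07-fold, at 99.8 ± 33.6 CPM in KC2, and Ambp 5.88-fold) and 5 lower. Stellate cell genes had 3 of 12 higher (Acta2, 3.88-fold) and 2 lower (Ecm1, 2.01-fold), 4 changed when adjusted over the list alone. Of 6 red blood cell genes 0 passed the edgeR test at an adjusted p under 0.05. Camera called the T and NK cell (adjusted p = 0.000543), neutrophil (0.00416) and cholangiocyte (0.0187) lists, which had adjusted p = 0.585, 0.585 and 0.596 with an estimated correlation. B cell markers had an adjusted p of 0.159, 0.0478 without KC2 replicate 1 and 0.0178 with the replicate number as a block. Without KC2 replicate 1 the log2 fold changes of Ms4a1 and Cd79a went from 5.72 to 4.97 and from 5.30 to 4.41, and without KC1 replicate 1 that of S100a9 went from 4.63 to 5.22 and that of Ltf from 6.61 to 8.02.

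Immune programmes differed. Interferon genes were lower in KC2, with 16 of 20 lower and 1 higher, and the interferon regulator Irf7 fell from 3573 ± 250 to 241 ± 84.7 CPM (14.8-fold) and Zbp1 12.7-fold. MHC class I presentation had 14 of 15 lower and 0 higher, with its activator Nlrc5 4.33-fold, Tap1 4.16-fold and H2-D1 2.05-fold lower. Camera gave adjusted p-values of 6.16e-07 and 6.22e-06, and adjusted p = 0.573 and 0.534 with an estimated correlation. MHC class II genes had 7 of 10 higher and 0 lower, with the class II activator Ciita at 169 against 26.0 CPM, H2-Oa 15.2-fold higher and Cd74 at 13069 ± 4482 against 7472 ± 925 CPM. The adjusted p of this list was 0.0767, and 0.00352 without KC2 replicate 1. Inflammatory genes had 6 of 19 higher (Il1b, 2.55-fold) and 7 lower (Il6 14.8-fold, Il18 13.7-fold). Checkpoint ligands and mediators had 4 of 22 higher (Nt5e, 14.7-fold) and 9 lower (Sirpa 4.22-fold, Ido1 at least 53.1-fold), with an adjusted p of 0.0527 that was under 0.05 without any one of 6 libraries, the lowest being 0.0281 without KC2 replicate 4, and 0.0375 with the replicate number as a block.

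Proliferation, stress and metabolic genes differed as well, with the same limit on the mix of RNA. Proliferation genes had 27 of 32 higher and 1 lower, at low levels for mitotic genes (Ccnb1 5.98 ± 3.38 against 1.01 ± 0.261 CPM) and higher levels for replication genes (Mcm3 121 ± 17.1 against 53.6 ± 9.69 CPM). Immediate early and dissociation genes, which respond within minutes to tissue handling, had 17 of 22 higher and 0 lower (Egr1 7.45-fold, Klf2 6.53-fold, Hspa1a 1.88-fold). Glycolysis genes had 11 of 17 lower (Hk2 4.71-fold, Pkm 3.11-fold) and 2 higher (Slc2a3, 23.3-fold). Camera gave adjusted p-values of 0.000540, 3.50e-05 and 0.000796 for these lists, and adjusted p = 0.574, 0.573 and 0.574 with an estimated correlation. Lipid uptake genes had 10 of 18 lower, including the liver X receptor Nr1h3 (1636 ± 61.0 to 117 ± 63.4 CPM) and Lrp1 (7.08-fold), and 3 higher, including Fabp5 (11.9-fold), with an adjusted p of 0.109 and of 0.0495 without KC2 replicate 1. Fatty acid oxidation had 7 of 15 higher (Acaa2, 2.15-fold) and 1 lower (Acadvl, 1.51-fold), 6 changed when adjusted over the list alone. Cholesterol and fatty acid synthesis had 11 of 25 higher and 7 lower (Acly, 1.62-fold). Oxidative phosphorylation had 7 of 27 higher (Ndufa1, 2.67-fold) and 8 lower (Cox5a, 2.72-fold), the unfolded protein response had 5 of 19 higher (Chac1, log2 fold change 4.66, and 6.35 without KC1 replicate 1) and 4 lower (Asns, 3.38-fold), and lipid-associated macrophage genes had 4 of 11 higher (Spp1) and 2 lower (Ctsd, 1.73-fold).

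Genes with the largest differences that were higher in KC2 were Cd209a, a C-type lectin gene of dendritic cells (44.9 ± 2.53 CPM, at least 883-fold), Cnmd (at least 419-fold), the copper oxidase Heph (at least 309-fold), the peptidase Enpep (190 ± 36.5 against 0.117 ± 0.114 CPM), Gpr141b (at least 203-fold), Retnla (77.2 ± 55.8 CPM), the lectin gene Mgl2 (893-fold) and Deup1 (count ratio 899, 161 to 35554). Lower genes included Calb2 (0 counts in KC2, at least 307-fold), the acute phase gene Saa3 (5718 ± 1573 to 9.60 ± 4.33 CPM), Zfp811, the growth factor Csf3, Ppm1n, Hydin and the protein C receptor Procr (1125 ± 241 to 12.0 ± 1.55 CPM). In total 7638 of 12774 tested genes differed, 4078 higher and 3560 lower, and 2827 and 1863 of these by at least 2-fold, and without KC2 replicate 1, which stood apart from the other KC2 libraries, 7804 differed. Replicates of KC1 and KC2 varied far more than those of the early HCC cells, and in simulated data with few planted changes the test recovered 32% of genes changed 2-fold. The adjusted p of C1qb was 0.0543 without KC1 replicate 3. Adjusted p-values of Trf, Cd74, Il1b and Hsp90b1 rose above 0.05 when any of several libraries was left out. In edgeR with the replicate number as a block they were 0.0507, 0.0785, 0.172 and 0.0584. That of Il1b was 0.111 with limma-voom, and that of Hsp90b1 was 0.0512 in edgeR without a filter.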

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

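The tests of this part were chosen after the endothelial result and the position of KC2 replicate 1 had been seen. Of 198 checked sets of 4 libraries, 23 (11.6%) were listed, 9 of them for KC2 replicate 1. In 6 of the 23 the other 3 libraries had 0 counts, which gives a ratio of 1 whatever the value. Of 174 sets without zeros 17 (9.77%) were listed, where chance alone gives about 1 in 20, and 7 of the 17 were KC2 replicate 1. A library was listed when its gap to the nearest other, divided by the whole range, was above the critical value for 4 samples.

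KC2 replicate 1 was far above the other KC2 libraries for Esam (887 CPM, median of the others 532, ratio of gap to range 0.942), Dnase1l3 (14354 and 6838 CPM, ratio 0.895), Hdac7 (129 and 78.5 CPM, ratio 0.844), and Alb (150 and 82.8 CPM, ratio 0.830), and alone in having counts of Mef2b (0.902 CPM, ratio 1) and Zfp811 (0.251 CPM, ratio 1). It was far below them for Lrp1 (49.7 and 257 CPM, ratio 0.889), C1qb (625 and 3965 CPM, ratio 0.842) and Ctsd (1636 and 2726 CPM, ratio 0.838). KC2 replicate 4 was alone in having counts of Hydin (0.426 CPM, ratio 1).

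KC1 replicate 2 was far above the other KC1 libraries for Mrc1 (285 and 99.0 CPM, ratio 0.870), Acly (360 and 241 CPM, ratio 0.983), Ctsd (5805 and 3712 CPM, ratio 0.855), Ciita (37.9 and 22.2 CPM, ratio 0.847) and Acaa2 (57.0 and 37.5 CPM, ratio 0.840), far below them for Ms4a4c (387 and 597 CPM, ratio 0.923), and alone in having counts of Mef2b (0.0652 CPM, ratio 1). KC1 replicate 1 was far above for Chac1 (1.66 and 0.139 CPM, ratio 0.954), Ms4a1 (1.17 and 0.416 CPM, ratio 0.900) and Hdac9 (133 and 116 CPM, ratio 0.834). KC1 replicate 4 was far above for Mef2d (53.9 and 43.4 CPM, ratio 0.884) and alone in having counts of Deup1 (0.0693 CPM, ratio 1), and KC1 replicate 3 was alone in having counts of Retnla (0.268 CPM, ratio 1).

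Endothelial transcripts were higher in KC2 than in KC1, and 3 technical explanations were weighed. In KC2 replicate 1, which had the lowest Kupffer cell list (1 of 25 members above the other KC2 libraries), 96.3% of the endothelial members were above the other KC2 libraries, which could come from RNA of sinusoidal endothelial cells, although cells carrying both programmes may give the same values. For a lower share of Kupffer cells that raised every other cell type alike, the endothelial and hepatocyte median log2 fold changes were compared. They differed by 5.81 (5.16 to 6.72 over resampled members), which argues against an equal rise of hepatocyte RNA only. Medians of the T and NK cell, cholangiocyte, B cell and neutrophil lists were 5.82, 5.25, 4.90 and 4.57, nearer the endothelial 6.68. Those of the monocyte, stellate cell and red blood cell lists were 2.05, 0.13 and -0.45. RNA of several other cell types in the KC2 libraries was therefore not excluded. A single unusual library was argued against, since without KC2 replicate 1 all 27 members were still higher.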

How the results depend on the processing

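The counts of differing genes stayed within 1.5 times the reported ones under every alternative: 6541 to 7962 for KO against WT, 8804 to 11890 for early HCC against normal liver and 5804 to 7956 for KC2 against KC1, and genes called both there and in the report kept their direction. The lowest counts came from the filter at 10 CPM, which left 9065, 9804 and 8920 genes to test. Without genes of chromosomes 4, 7 and 9, a setting chosen after the data were seen, 5996 of 9738 tested genes differed between KO and WT. The counts of gene lists past the threshold (4, 4 and 11 with camera) depended on the test. With an estimated inter-gene correlation they were 1, 0 and 0 (unadjusted, 2, 3 and 1 of 28, 30 and 27), and with fry 25, 29 and 18. The replicate block gave 4, 3 and 13: the hepatocyte list of early HCC against normal liver was lost (adjusted p = 0.0590), and the checkpoint (0.0375) and B cell (0.0178) lists of KC2 against KC1 were gained. Camera compares a list with the other genes and fry tests its members alone, and the cause of each change was not tested. Under fry the directions of 3 lists of early HCC against normal liver were opposite to those of camera: glycolysis (adjusted p = 0.0462), unfolded protein response (0.000254) and inflammatory genes (0.000148). A change of sign between 2 values that both missed the threshold was not counted. The correlation of the 2 early HCC comparisons was -0.295 among genes of at least 10 CPM and -0.264 to -0.254 leaving out each library in turn, and the cause was not tested. Libraries of the same number showed r of -0.13 to 0.09 within comparisons, so the number was not taken as a pairing, and the block gave 7962, 10911 and 7287 differing genes. Depth sets a floor of 0.150 to 0.208 CPM for 3 counts in 1 library, and fold changes of genes with few counts in 1 group moved by over 1.5 times when a library was left out.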

Other observations

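Against WT cells, KO cells had lower Ngfr, a stellate cell receptor (5.76-fold, 3.44 against 19.9 CPM), and stellate markers had 3 of 5 tested members lower and 0 higher. Kupffer cell identity genes had 3 of 7 lower (Id3, 2.52-fold) and 1 higher, the lysosomal gene Cd68 (2.29-fold). Endothelial markers had 3 of 7 lower (Egfl7, 1.34-fold) and 1 higher (Mmrn2, 2.13-fold). T and NK cell markers had 2 of 3 lower (Lck, 3.87-fold), neutrophil markers 4 of 5 lower and 1 higher (Cxcr2, 1.31-fold), and monocyte markers 3 of 4 higher (Vcan, 1.74-fold) and 1 lower. Of the lower members, S100a8 had an adjusted p of 0.0949 with DESeq2 and of 0.0644 to 0.141 without any one of WT replicates 1 and 2 and KO replicates 2 and 3, and Cd8a had 0.0674 with DESeq2 and 0.0520 without KO replicate 3. Mean CPM over the T and NK cell list summed to 5.27 in KO and 7.97 in WT cells. The leukocyte gene Ptprc averaged 0.0959 and 0.0945 CPM, so these counts do not show leukocytes among the cells. Of the lists too small for camera, Cebpa fell 1.46-fold (adjusted p = 0.0285, but 0.0563 with DESeq2 and 0.0685 to 0.148 without any one of WT replicates 1 and 2 and KO replicates 2 and 3), Por fell 1.32-fold, Slc4a1 fell 4.40-fold, and 0 of 2 B cell markers and 0 of 1 sex-linked genes passed the edgeR test.

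Against normal liver cells, early HCC cells had lower Igfbp7 (0.381 ± 0.0769 against 316 ± 19.9 CPM), Krt7, a biliary keratin (0.361 ± 0.178 against 409 ± 5.93 CPM), and Plac8 (0.135 ± 0.0929 against 354 ± 8.47 CPM). Endothelial markers had 7 of 12 lower and 5 higher, cholangiocyte markers 5 of 7 lower and 2 higher (Spp1, 8.18-fold), Kupffer cell identity genes 5 of 10 lower (Nr1h3, 98.6-fold) and 3 higher, and monocyte markers 4 of 5 higher (Fn1, 3.24-fold) and 1 lower. Stellate markers had 5 of 5 higher (Des, 20.8-fold), T and NK cell markers 3 of 3 (Cd8a, 6.73-fold) and neutrophil markers 3 of 5 (S100a8, 10.1-fold). Levels of these 3 genes were low in the early HCC libraries: Des at 8.07, 9.63 and 13.4 CPM, Cd8a at 3.12, 3.43 and 3.16 CPM, and S100a8 at 1.72, 1.35 and 1.01 CPM. The leukocyte gene Ptprc averaged 0.0945 CPM in the WT and 0.659 CPM in the normal liver libraries, so these folds do not show leukocytes among the early HCC cells. Immediate early genes had 10 of 22 higher (Hsp90aa1, 1.43-fold) and 10 lower. Slc4a1 and the Y-linked Uty (1.97-fold) were higher, and 0 of 1 B cell markers passed the edgeR test. Uty was the only sex-linked gene tested. The Y-linked Ddx3y and Kdm5d had no row and Eif2s3y was at most 0.482 CPM. The fold of Uty therefore does not show a rise of Y-linked genes in general. In KC2 against KC1, sex-linked genes had 3 of 4 lower (Uty, 2.09-fold). Chromosome medians between early HCC and normal liver cells lay furthest from that of all genes on chromosomes 19 (-0.93), 18 (-0.58) and 14 (0.50).

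The tests of chromosomes and of normal liver cells were all chosen after the chromosome medians and the normal liver values had been seen. Genes of whole chromosomes moved together between KO and WT cells, and 3 explanations were weighed. The chromosome 4 median was 0.44 or more above that of all genes at each of 3 levels of expression, which could come from a difference in copy number between the cell populations, although DNA was not measured. GC content and gene length were argued against, since the median was 0.496 after correction. Loss of a DNA segment in WT cells could give the run of 6 neighbouring genes near zero there, where shuffled orders gave at most 3, but 7 clustered Pcdhb genes near zero in WT and present in normal liver cells (shuffled, at most 6) show that regulation of a cluster may give such runs too. The 6 neighbouring genes near zero in WT cells, Lrrc47 among them, were at 5.92 to 70.1 CPM in normal liver cells. Whether KO and WT cells came from the same parent population was not tested, and this bears on every KO and WT call. No biological effect of Mef2d on whole chromosomes was tested.

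Hepatocyte transcripts were scarce in the normal liver libraries, and 3 explanations were weighed. Mature hepatocyte RNA as the main source was argued against by a highest value of 2.64 CPM for Alb, 1.05 for Apoa1 and 0.165 for Cps1. For loss of hepatocyte transcripts in counting, Alb was at 99.8 CPM in KC2. The Kupffer cell table may have been counted differently, with 83.4% to 84.7% whole values against 31.8% to 35.3% in the normal liver table. Alb in KC2 therefore cannot decide whether such transcripts were lost from the normal liver table. The argument from Alb, Apoa1 and Cps1 above assumes that they were counted. Leukocyte or endothelial RNA as the main source was argued against by the means of Ptprc, 0.659 CPM, and Pecam1, 0.0182 CPM, and by Kdr, Stab2 and Tie1 of at most 0.220, 0.110 and 0 CPM, although Igfbp7, Ptprb and Adam23 were at 316, 72.9 and 62.9 CPM. Whether the normal liver cells were cultured or biliary-like was not tested. The WT early HCC libraries had lower means of Alb (0.133 CPM) and Apoa1 (0.115 CPM) than the normal liver libraries. Their relation to hepatocytes was not tested either.

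Other splits of the libraries were also tested with edgeR. For KO and WT, 1 of 10 splits, the real one, had as many calls (7800, highest other 0, and 85 unadjusted), and for early HCC and normal liver 1 of 10 (11069, highest other 0, and 8 unadjusted). These splits are too few to tell. For KC2 and KC1, 1 of 35 splits had as many (7638, highest other 0, and 772 unadjusted), so a chance division of the libraries was argued against.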
